A study of Homo sapiens with 5 samples.

How the data were processed

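The series profiled chromatin of MOLT-4 cells, an established human T cell acute lymphoblastic leukaemia line, by CUT&RUN. In this assay an antibody directs a protein A/G-micrococcal nuclease fusion to a chromatin protein or histone mark, and the fragments released by the nuclease are sequenced. Per the labels, libraries were sequenced as paired-end reads and 5 samples were made: libraries for H3K4me3, RUNX1 and a target labelled SMA4, and 2 controls whose antibody is given as IgG and whose titles call them input. The title of 1 control names H3K4me3, and that of the other names no target. The SMA4 label does not spell out the target, so its name is used here as given. Peak lists of 3 libraries were analysed. Peak lists of the 2 IgG samples were not used here. Each antibody had 1 library, so no result has a replicate check, and every test compares lists of peaks from single libraries, not conditions.

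The authors deposited 1 peak list per library, as 4 columns: chromosome, start, end and a running peak name. The lists hold no fold enrichment, p-value, q-value, summit or read count, so the read depth behind a peak is unknown. Per the file headers, the H3K4me3 and RUNX1 peaks came from MACS2, and the headers point to signal tracks, control-subtracted and scaled to library size, in a folder named for batch 2. Peak names in both lists carry tags for deduplicated and unique reads and a further tag, p03, that no source used here explains. Per the file headers, the SMA4 peaks came from cutruntools with a q threshold of 0.01 on fragments of all lengths, in a folder named for batch 3 that also holds a 120 bp fragment track. The SMA4 header, like those of the other lists, points to a control-subtracted signal track scaled to library size. The submitters' processing notes name MACS2, SEACR and the hg19 genome, without versions or roles. The threshold of the H3K4me3 and RUNX1 lists, which sets how many peaks they hold, the aligner and which control was subtracted from which library are not given in the sources used here. The SMA4 list therefore differs from the other lists in antibody, batch and peak-calling pipeline at once, and these cannot be told apart. Numbers of peaks and widths are compared within a list, never read as differences in binding between lists.

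Coordinates are those of the deposited lists in hg19, written 1-based. An annotation of hg19 was not used here, and the gene table at hand belongs to GRCh38, so no peak was assigned to a gene, promoter or motif. The tests planned for promoters, gene lists and motifs, and those at a stricter q threshold or at summits, were not run. The plan also used the peak caller's fold to rank and compare peaks. Peak width, planned as the alternative, took its place.

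Peaks on chromosomes 1 to 22 and X were used. A peak overlapped another when they shared at least 1 bp. Observed overlap was compared with 10000 circular shifts, each moving all peaks of the first list on a chromosome by 1 random offset, with the highest peak end in the 3 lists as the chromosome's length. Shifts keep peak number, width and spacing, but can place peaks in unmappable sequence. The two-sided permutation p counted shifts at least as far from their mean as the observed share, so the smallest p it can give is 1e-04. Associations between overlaps within a list were tested with Fisher's exact test (two-sided), and widths with a permutation test of the mean rank (100000 resamples, two-sided). Chromosome densities were compared over 23 chromosomes by Pearson's r and Spearman's rho, each with a permutation p from 100000 resamples. Benjamini-Hochberg adjustment was applied within each family of 6 overlaps, 3 Fisher tests, 6 width comparisons, 12 correlations and 3 position tests. Intervals on shares are 95% Wilson intervals. They cover counting error only, and neighbouring peaks are not independent. Ratios of medians and rho have 95% bootstrap intervals from 2000 draws.

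The rule for named peaks, with width in place of fold, took the 10 widest peaks of each list and the 10 SMA4 peaks overlapping both other lists with the lowest sum of width ranks. Regions of neighbouring peaks, joined at the default stitching distance of the ROSE method for grouping enhancers, were added after the lists had been seen, with the 10 richest named by bases in RUNX1 peaks or by number of SMA4 peaks.

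Alternatives fixed before the data were examined were an overlap of at least 50% of the shorter peak, peaks within 1 kb, all sequences in the files, random shifts of 10 to 100 kb for each peak, and merging of touching peaks. Alternatives added afterwards were overlap at peak midpoints, equal numbers of the widest peaks, removal of peaks at the minimum width, SMA4 regions in place of peaks, and strata of RUNX1 or H3K4me3 width. The comparisons of SMA4 widths, of H3K4me3 widths by SMA4, of SMA4 overlap of H3K4me3 peaks by RUNX1, of 4 width classes of equal size and of chromosome densities were also added after overlaps, widths and densities had been looked at. Alternatives used 1000 shifts each. Overlap counting was checked against bedtools 2.31.1 and gave equal counts in 12 of 12 comparisons. On 100 simulated SMA4 lists of 1475 peaks placed at random, the shift test gave p under 0.05 in 3% of lists, and in 100% of 100 lists with 5% of peaks planted on RUNX1 peaks. On RUNX1 widths, 6% of 50 unchanged splits and 100% of 50 splits with marked peaks widened by a factor of 1.3 passed the rank test. Simulated peaks were placed independently, marked peaks were drawn regardless of width, and fewer resamples were used than in the main tests. The simulations therefore cover neither the grouping of real SMA4 peaks nor the readier contact of wide peaks. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6.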

Results

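MOLT-4 cells were profiled by CUT&RUN for H3K4me3, a histone mark of active and poised promoters, for RUNX1, a runt-domain transcription factor of blood cells, and for the target labelled SMA4. The deposited lists held 13199 H3K4me3 peaks, 36777 RUNX1 peaks and 1479 SMA4 peaks, each from 1 library without replicates. On chromosomes 1 to 22 and X, 13181 H3K4me3, 36736 RUNX1 and 1475 SMA4 peaks remained. H3K4me3 peaks covered 14.0 Mb with a median width of 938 bp (quartiles 355 and 1524 bp). RUNX1 peaks covered 29.2 Mb with a median width of 645 bp (quartiles 380 and 1024 bp). SMA4 peaks covered 0.396 Mb with a median width of 219 bp (quartiles 174 and 316 bp). The narrowest peaks were 179 bp for H3K4me3, 221 bp for RUNX1 and 141 bp for SMA4, and 7.45%, 4.73% and 1.15% of the lists were exactly that wide. The peak lists give no read depth, and the SMA4 list came from another batch and pipeline than the other lists.

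The first comparison asked where RUNX1 peaks lay relative to H3K4me3. RUNX1 peaks were found at most H3K4me3 peaks, whereas most RUNX1 peaks lay outside the mark. The RUNX1 list is larger, with 36736 against 13181 peaks, which by itself lowers the share of its peaks at the mark. Control peaks were not compared with the mark, so the overlap has no IgG value beside it. Of 13181 H3K4me3 peaks, 11616 overlapped a RUNX1 peak (88.1%, 95% interval 87.6 to 88.7%). Of 36736 RUNX1 peaks, 11846 overlapped an H3K4me3 peak (32.2%, 95% interval 31.8 to 32.7%) and 24890 did not. Circular shifts gave 2.42% for the H3K4me3 peaks and 0.886% for the RUNX1 peaks, so the observed shares were 36.4 times chance in both directions. Both had a permutation p of 1e-04 (adjusted p = 1e-04), the smallest that the shifts can give. When each RUNX1 peak was instead moved by 10 to 100 kb, chance rose to 1.93% and the ratio fell to 16.7, and it was 20.4 with peaks within 1 kb counted as overlapping. With the 1475 widest peaks of each list the ratio was 113.

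**Figure D1:**
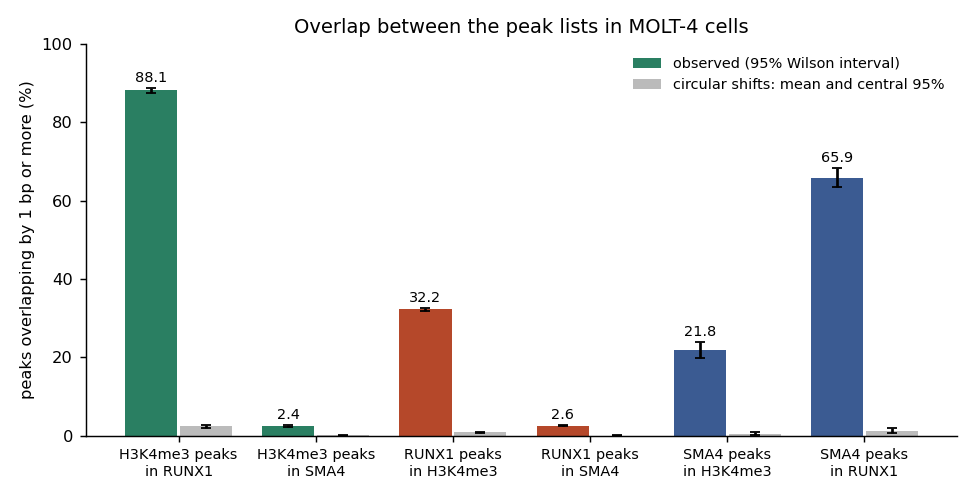
Share of the peaks of each list that overlap a peak of another list (percent; coloured bars, 95% Wilson intervals), beside the share after circular shifts (grey bars, mean and central 95% of 10000 shifts). The H3K4me3 peaks overlapping RUNX1 (88.1%) and the SMA4 peaks overlapping RUNX1 (65.9%) are the tallest bars, and the grey bars reach 2.42% at most.

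H3K4me3 peaks with RUNX1 were wider than those without, and RUNX1 peaks with H3K4me3 were wider than those without. H3K4me3 peaks overlapping RUNX1 had a median width of 1066 bp against 221 bp for the 1565 others, a ratio of 4.82 (95% interval 4.63 to 5.01). The lower quartile of those others was 179 bp, the minimum width of the list, so many of them were the narrowest peaks called. Width comparisons were not repeated without peaks at the minimum width. RUNX1 coverage of the mark went from 62.8% in the narrowest of 4 equal width classes of H3K4me3 peaks to 91.3%, 98.5% and 99.9% in the wider classes. In the widest class, 3291 of 3295 H3K4me3 peaks overlapped RUNX1. RUNX1 peaks overlapping H3K4me3 had a median width of 1012 bp against 527 bp, a ratio of 1.92 (95% interval 1.89 to 1.95). The share of RUNX1 peaks with H3K4me3 was 12.3% in the narrowest class and 63.3% in the widest. Both width differences passed the permutation test of ranks (p = 1e-05, the smallest it can give; adjusted p = 1.5e-05). A wide peak also meets other peaks more readily. With overlap counted at the H3K4me3 midpoint, the ratio for H3K4me3 peaks was 2.78.

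**Figure D2:**
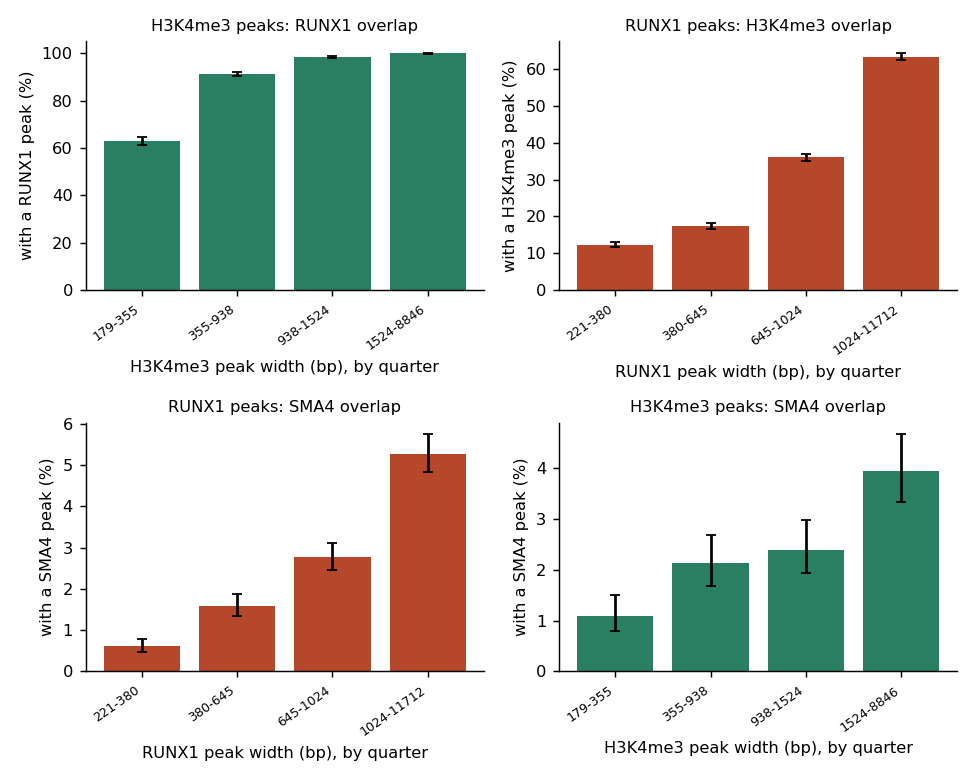
Share of peaks that overlap another list (percent, vertical axes; 95% Wilson intervals) in 4 equal classes of peak width (bp, horizontal axes), for H3K4me3 peaks and for RUNX1 peaks. Overlap with RUNX1 goes from 62.8% to 99.9% across the classes of H3K4me3 width, and overlap of RUNX1 peaks with SMA4 from 0.610% to 5.27%.

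The widest H3K4me3 peak lay on chromosome 7 from 92459580 to 92468425 (8846 bp) and overlapped 5 RUNX1 peaks and 1 SMA4 peak. It was followed by peaks on chromosome 6 from 32935330 to 32942325 (6996 bp), chromosome 5 from 133449624 to 133456561 (6938 bp) and chromosome 21 from 36255850 to 36262703 (6854 bp). All 10 of the widest H3K4me3 peaks overlapped RUNX1, and 3 overlapped SMA4. Among the 10 widest RUNX1 peaks, 6 overlapped H3K4me3 and 3 overlapped SMA4. The widest RUNX1 peak spanned 11712 bp on chromosome 9 from 132646407 to 132658118 and overlapped 7 H3K4me3 peaks and 1 SMA4 peak. The second, on chromosome 4 from 109086090 to 109095910 (9821 bp), overlapped 5 H3K4me3 peaks and 1 SMA4 peak. The third, on chromosome 14 from 98660985 to 98670708 (9724 bp), overlapped neither. A RUNX1 peak on chromosome 17 from 56409543 to 56417957 (8415 bp) ran into one of the widest H3K4me3 peaks, at 56406035 to 56411617 (5583 bp).

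Many RUNX1 peaks had another RUNX1 peak nearby. Neighbouring peaks were joined into regions, a step added after the lists had been seen. The 36736 peaks formed 20665 regions, and 7486 regions of 2 or more peaks held 64.1% of all RUNX1 peaks. The same share was 46.1% in the shorter H3K4me3 list and 22.3% in the SMA4 list. A longer list joins more peaks by density alone, and no chance value was computed, so this does not show grouping particular to RUNX1. The region with the most bases in RUNX1 peaks lay on chromosome 21 from 36334788 to 36432496. It held 32 RUNX1 peaks with 42.1 kb in peaks, 2 H3K4me3 peaks and no SMA4 peak. The next, on chromosome 17 from 55508565 to 55630201, held 43 RUNX1 peaks and 1 H3K4me3 peak. A region on chromosome 1 from 230238937 to 230325663 held 30 RUNX1 peaks and was the only one of the 10 named RUNX1 regions without H3K4me3. Of these 10 regions, 4 held an SMA4 peak. H3K4me3 was present in 36.2% of single-peak RUNX1 regions (95% interval 35.3 to 37.0%), in 51.4% of regions of 2 to 4 peaks and in 66.2% of regions of 5 or more (95% interval 63.3 to 68.9%). Larger regions also span more sequence, with a median of 23.8 kb for 5 or more peaks against 0.66 kb for single peaks.

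The second comparison asked where SMA4 peaks lay relative to RUNX1. Most SMA4 peaks fell on RUNX1 peaks. Few RUNX1 peaks carried SMA4, but a list of 1475 SMA4 peaks is too short to reach most of 36736 RUNX1 peaks. Of 1475 SMA4 peaks, 972 overlapped RUNX1 (65.9%, 95% interval 63.4 to 68.3%) against 1.25% in circular shifts, a ratio of 52.7 (permutation p = 1e-04; adjusted p = 1e-04). With random moves of 10 to 100 kb the ratio was 26.1, and with peaks within 1 kb it was 21.5. In the other direction, 940 of 36736 RUNX1 peaks overlapped SMA4 (2.56%, 95% interval 2.40 to 2.73%), 51.4 times the 0.0498% given by shifts. The size of the SMA4 list limits this share, so it does not show that the other RUNX1 peaks lack the target. When only the 1475 widest peaks of each list were kept, 12.1% of SMA4 peaks overlapped RUNX1, 84.3 times chance. RUNX1 peaks with SMA4 had a median width of 1056 bp against 635 bp without, a ratio of 1.66 (95% interval 1.56 to 1.76; permutation p = 1e-05, adjusted p = 1.5e-05), and the ratio was 1.3 with overlap counted at the RUNX1 midpoint. SMA4 peaks in RUNX1 were slightly wider than those outside (224 against 210 bp, adjusted permutation p = 8.5e-04).

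The third comparison asked whether SMA4 lay at H3K4me3. SMA4 peaks overlapped the mark less often than they overlapped RUNX1, and nearly all that did so also overlapped RUNX1. The RUNX1 list is larger, with 36736 against 13181 peaks, which by itself makes overlap with it more frequent. Relative to shifts, the ratios were 52.7 for RUNX1 and 39.4 for H3K4me3, a difference that was not tested. The order stayed the same with peaks within 1 kb, at 21.5 and 19.6. It turned round with random moves of 10 to 100 kb, at 26.1 for RUNX1 and 29.1 for H3K4me3. The ratios therefore do not show a preference for either list. Of 1475 SMA4 peaks, 321 overlapped H3K4me3 (21.8%, 95% interval 19.7 to 23.9%), 39.4 times the 0.553% given by shifts (permutation p = 1e-04; adjusted p = 1e-04), or 19.6 times chance with peaks within 1 kb. With the 1475 widest peaks of each list, 5.83% of SMA4 peaks overlapped H3K4me3. SMA4 peaks with and without H3K4me3 had median widths of 218 and 220 bp, a difference that did not pass the test (ratio 0.99, 95% interval 0.93 to 1.05; adjusted permutation p = 0.76). By class, 310 SMA4 peaks overlapped both other lists, 662 RUNX1 alone, 11 H3K4me3 alone and 492 neither.

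Within the SMA4 list, 96.6% of the peaks at H3K4me3 overlapped RUNX1 against 57.4% of the others (odds ratio 20.9, 95% interval 11.4 to 42.8). Fisher's exact test gave p = 9.0e-50 (adjusted p = 2.7e-49), with peaks counted as independent. The odds ratio was 8.24 with the 1475 widest peaks of each list and 34.9 with peaks within 1 kb counted as overlapping. Among H3K4me3 peaks, 2.64% of those with RUNX1 carried SMA4 against 0.511% of those without, a difference that passed Fisher's exact test (odds ratio 5.28, 95% interval 2.64 to 12.4; adjusted p = 2.7e-09). H3K4me3 peaks with SMA4 were also wider (median 1321 against 929 bp), and over 10 strata of H3K4me3 width the pooled odds ratio was 2.84 (95% interval 1.37 to 5.88; Mantel-Haenszel chi-square test, p = 0.0028). Only 8 H3K4me3 peaks had SMA4 without RUNX1. Among RUNX1 peaks, 2.84% of those with H3K4me3 and 2.42% of those without carried SMA4 (odds ratio 1.18, 95% interval 1.03 to 1.35; Fisher's exact test, adjusted p = 0.018). This last difference turned round once RUNX1 width was taken into account. Over 10 strata of width, the pooled odds ratio was 0.583 (95% interval 0.504 to 0.673; Mantel-Haenszel chi-square test, p = 3.2e-14), with SMA4 rarer at RUNX1 peaks with H3K4me3. When peaks within 1 kb counted as overlapping, the odds ratio was 0.998 (Fisher's exact test, p = 1).

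The named peaks shared by the 3 lists were led by an SMA4 peak on chromosome 5 from 43042165 to 43042488. It lay in a RUNX1 peak of 4291 bp from 43039388 and an H3K4me3 peak of 3831 bp from 43039248. The second was on chromosome 1 from 158301858 to 158302150, within a RUNX1 peak of 3026 bp. The third was on chromosome 5 from 96270801 to 96271062, within a RUNX1 peak of 3555 bp. Of the 10 widest SMA4 peaks, 4 overlapped RUNX1 and 2 overlapped H3K4me3. In the widest of 4 equal width classes of the SMA4 list, 263 of 369 peaks (71.3%) overlapped RUNX1, against 59.1% in the narrowest. The widest, on chromosome 5 from 120360068 to 120361737 (1670 bp), and the second, on chromosome 3 from 162437148 to 162438657 (1510 bp), overlapped neither list. The third, near the start of chromosome 5 from 10172 to 11399 (1228 bp), also overlapped neither. Peaks in sequence prone to mapping artefacts were not removed here, so such wide peaks need not mark binding.

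SMA4 peaks formed 1283 regions, of which 137 held 2 or more peaks and together 22.3% of the list. The region with the most, on chromosome 3 from 35674786 to 35706247, held 14 SMA4 peaks, of which 10 overlapped RUNX1 and 3 overlapped H3K4me3. It contained an H3K4me3 peak of 5905 bp from 35680506 to 35686410, one of the 10 widest. The second held 7 SMA4 peaks on chromosome 3 from 151911129 to 151922444, and the third 6 on chromosome 1 from 198990228 to 199011704. Of the 10 named SMA4 regions, 9 held a RUNX1 peak and 4 held an H3K4me3 peak. The exception, on chromosome 1 from 91023185 to 91028932, held 4 SMA4 peaks and no peak of the other lists.

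**Figure D3:**
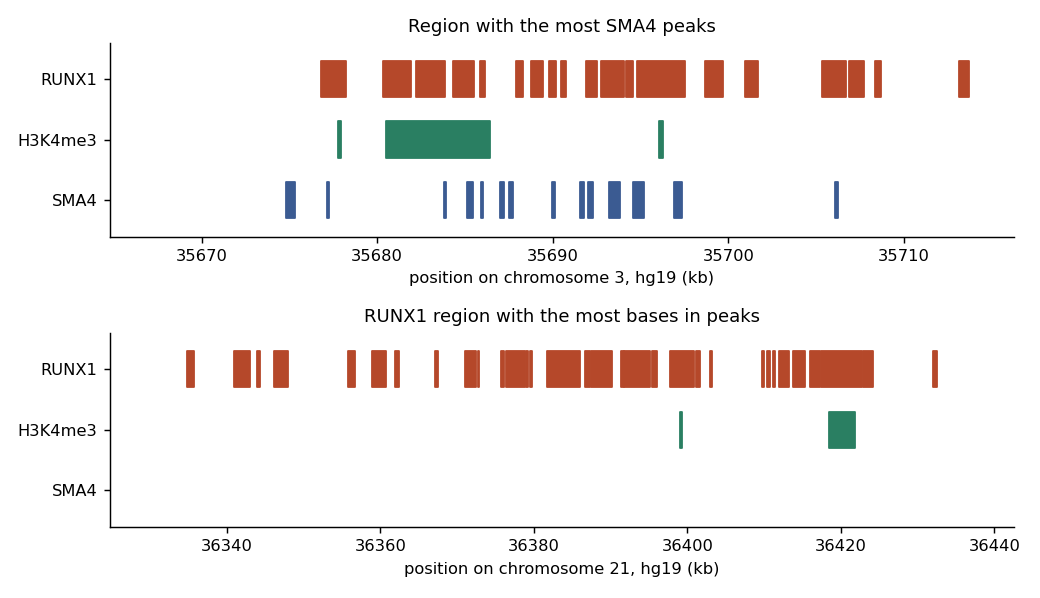
Peaks of the 3 lists (boxes, drawn to scale) in 2 regions with 10 kb on either side, against position in kb in hg19. The region on chromosome 3 holds 14 SMA4 peaks among RUNX1 peaks and 3 H3K4me3 peaks, and the region on chromosome 21 holds 32 RUNX1 peaks, 2 H3K4me3 peaks and no SMA4 peak.

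The lists were also spread differently over the chromosomes. RUNX1 and H3K4me3 peaks were densest on chromosome 19, at 26.8 and 16.4 peaks per Mb, and on chromosome 17, at 26.3 and 10.1 peaks per Mb. SMA4 peaks were densest on chromosome 1, at 0.678 peaks per Mb, and had 0.271 and 0.296 peaks per Mb on chromosomes 19 and 17. These 2 chromosomes held 13.5% of H3K4me3 peaks, 10.1% of RUNX1 peaks and 2.71% of SMA4 peaks (95% interval 2.0 to 3.7%). Across 23 chromosomes, RUNX1 and H3K4me3 densities were correlated (Pearson's r = 0.92, Spearman's rho = 0.94; permutation p = 1e-05, adjusted p = 6.0e-05 for both), with r = 0.90 without chromosomes 17 and 19. No correlation of RUNX1 and SMA4 densities passed the test (r = -0.35, permutation p = 0.11, adjusted p = 0.21; rho = -0.30, 95% interval -0.71 to 0.16, p = 0.17, adjusted p = 0.23), with r = -0.059 without the same chromosomes. H3K4me3 and SMA4 gave r = -0.40 (permutation p = 0.048, adjusted p = 0.11) and rho = -0.31 (p = 0.15, adjusted p = 0.22), with r = -0.16 without them. Chromosome X had the lowest density of both RUNX1 and SMA4 peaks, at 5.84 and 0.213 per Mb, which pulls their correlation upward. No correlation was computed without it, so the values do not show that the 2 densities are unrelated. The difference between these correlations was not tested.

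**Figure D4:**
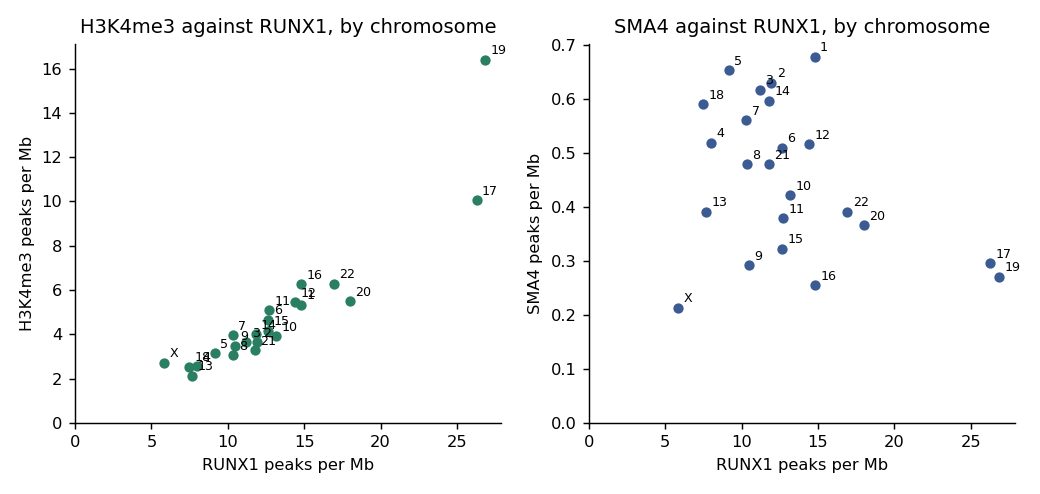
Peaks per Mb on each of 23 chromosomes (points, labelled), H3K4me3 against RUNX1 on the left and SMA4 against RUNX1 on the right. Chromosomes 17 and 19 have the highest RUNX1 and H3K4me3 densities, and SMA4 densities of 0.296 and 0.271 per Mb.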

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

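The patterns weighed here were found in the data. The test of random placement inside H3K4me3 peaks was chosen after its observed share had been seen, while the other tests were set before the values they measure were known.

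The RUNX1 list held 9 peaks on the mitochondrial genome, a sequence used only in the alternative that took all sequences. They covered 13227 bp and reached base 16571. The H3K4me3 and SMA4 lists each held 0, and a count of 0 allows up to 3 peaks if peaks are independent. These lists are also shorter, with 13199 and 1479 peaks against 36777, so the counts do not show a difference in mitochondrial signal.

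Most SMA4 peaks lay on RUNX1 peaks, yet no correlation of their densities across chromosomes passed the test (rho = -0.30). If a few regions with many SMA4 peaks set the densities, counting neighbouring peaks as 1 region should have given a rho of 0.4 or more, but it was -0.28 (95% bootstrap interval -0.70 to 0.22), and -0.11 (-0.59 to 0.39) without chromosomes 17 and 19. If SMA4 peaks outside RUNX1 hid the trend of the rest, the peaks inside RUNX1 should have reached 0.4 too, but gave rho = -0.16 (95% interval -0.57 to 0.28). Without chromosomes 17 and 19 this was -0.029 (-0.49 to 0.43) with r going from -0.16 to 0.13. With chromosome X kept, the evidence against this explanation thus rests on chromosomes 17 and 19. Chromosome X, lowest in RUNX1 and in SMA4 density, was kept in all values given here. None was computed without it, so how far they rest on it was not tested. The peaks outside RUNX1 gave rho = -0.45 (permutation p = 0.033, adjusted p = 0.098) and r = -0.49 (permutation p = 0.015, adjusted p = 0.059), neither past the threshold after adjustment, with r = -0.27 without the same chromosomes. A preference of the target, the other batch and the other peak-calling pipeline remain open, since all of them go with the SMA4 library.

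RUNX1 peaks at H3K4me3 were 1.92 times as wide as the others. If wide peaks merely met the mark more often by chance, the ratio should have fallen under 1.1 once overlap was counted at the RUNX1 midpoint. It was 1.86 (95% interval 1.83 to 1.89), which argues against chance contact as the whole cause. Whether more fragments, several neighbouring sites or general cleavage of open promoters widen these peaks stays untested, as reads and IgG peaks were not used here.

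SMA4 overlaps with RUNX1 and with H3K4me3 went together. Because RUNX1 covers most of the mark, SMA4 peaks placed at random inside the same H3K4me3 peaks met RUNX1 in 82.1% of cases (central 95% of placements 78.5 to 85.7%). The observed share was 96.6% (permutation p = 1e-04, the smallest that 10000 placements can give), so that coverage alone falls short of it. The rest may reflect a shared open centre of promoters or binding of both targets. The design does not separate these.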

How the results depend on the processing

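Of 44 alternative values with a test, 42 kept the direction and the side of the 0.05 threshold. Merging touching peaks moved none of the 3 peak numbers, since the lists hold 0 touching neighbours, and says nothing about stability. The share of RUNX1 peaks at H3K4me3 ranged from 28.5 to 35.1% over 7 alternatives, at 16.7 to 113 times chance. The share of SMA4 peaks at RUNX1 ranged from 12.1 to 68.9% over 8, at 21.5 to 84.3 times chance, and that at H3K4me3 from 5.83 to 24.7%, at 19.6 to 43.8 times chance. Both low SMA4 shares came from keeping the 1475 widest peaks per list, a setting added after seeing the data that by construction removes most RUNX1 and H3K4me3 peaks. The lowest ratios to chance came from random moves of 10 to 100 kb for RUNX1 at H3K4me3 and from counting peaks within 1 kb for SMA4. The odds ratio between RUNX1 and H3K4me3 overlap of SMA4 peaks ranged from 8.24 with the 1475 widest peaks per list to 34.9 with peaks within 1 kb. The odds ratio of SMA4 at H3K4me3 peaks with against without RUNX1, 5.28 as listed, ranged from 2.84 when stratified by H3K4me3 width to 5.96, over 3 settings added after seeing the data. The ratio of median widths with against without overlap ranged from 1.80 to 1.95 for RUNX1 peaks by H3K4me3 and from 2.78 to 5.37 for H3K4me3 peaks by RUNX1. For RUNX1 peaks by SMA4, 1.66 as listed, it ranged from 1.3 with overlap counted at the RUNX1 midpoint, a setting added after seeing the data, to 1.70, and was 1.45 within 1 kb. The 2 values that changed belong to the odds ratio of SMA4 at RUNX1 peaks with against without H3K4me3, 1.18 as listed. It was 0.998 with peaks within 1 kb of each other, for which the cause was not tested, and 0.583 when stratified by RUNX1 width, a setting added after seeing the data. Since RUNX1 peaks at H3K4me3 were wider and wide peaks met SMA4 more often, the stratified value compares peaks of like width. The settings at a stricter q threshold, at summits, for promoters, gene lists and motifs were not run, for lack of those columns or of an hg19 annotation. Without replicates or read depth, no setting tests how far the lists would change in a second library.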

Other observations

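The comparison of chromosomes 17 and 19 and the classes of RUNX1 regions were chosen after the data had been seen. Part of the SMA4 list lay away from the other lists: 492 peaks (33.4%) overlapped neither RUNX1 nor H3K4me3, and the nearest RUNX1 peak was at a median of 50.6 kb (quartiles 9.63 and 209 kb). Overlap with RUNX1 was 59.1% in the narrowest of 4 width classes of SMA4 peaks (95% interval 54.0 to 64.0%) and 71.3% in the widest (66.5 to 75.7%). Overlap with H3K4me3 was 21.4% in both. On chromosomes 17 and 19, 19 of 40 SMA4 peaks (47.5%) lay at H3K4me3, against 21.0% of the 1435 elsewhere (Fisher's exact test, two-sided, p = 2.7e-04). These chromosomes were picked for their RUNX1 and H3K4me3 density, and more H3K4me3 there makes any overlap more frequent by position alone. The comparison does not correct for that density.

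Larger RUNX1 regions held SMA4 more often: 2.69% of single-peak regions (95% interval 2.42 to 2.98%), 5.51% of regions of 2 to 4 peaks and 14.9% of regions of 5 or more (12.9 to 17.2%). Per RUNX1 peak, however, the rate was 2.69%, 2.38% and 2.71% in the same classes, with overlapping 95% intervals. The rate per RUNX1 peak thus showed no rise with the size of the region.

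One hypothesis was that SMA4 peaks lie near the centre of the RUNX1 peaks they fall in. Of 929 SMA4 midpoints inside RUNX1 peaks, 729 were in the central 50% of the peak (78.5%, 95% interval 75.7 to 81.0%), where an even spread gives 50%. The interval lay above that value. The same shares were 61.4% for SMA4 in H3K4me3 peaks (55.7 to 66.7%) and 69.0% for RUNX1 in H3K4me3 peaks (68.1 to 69.9%). SMA4 positions are thus consistent with the RUNX1 peak centre, while a shared centre of open chromatin would give the same picture and was not tested.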
